A study of Mus musculus with 76 samples.

How the data were processed

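RNA was extracted from flash-frozen heart, kidney and visceral adipose tissue with the Qiagen RNeasy Plus Universal kit, and Illumina libraries were read as 2 reads of 50 bases per fragment, per the labels' protocols. Reads were trimmed and aligned before deposit. Trimmomatic 0.38, HISAT2 2.1.0, DESeq2 1.20.0 and 1.20.1 and the mouse build GRCm38 are named, with no role or order, per the submitters' processing notes. The counting tool, the aligner settings, strandedness and the annotation release are not given in the sources used here, so overlapping, antisense and near-identical genes cannot be told apart with certainty.

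The deposited tables hold raw read counts per gene, made by the authors with no normalization, for 54232 genes in 76 libraries. The deposited normalized table is a signal that the authors made by dividing each library's counts by 1 size factor, and the values equal the median-of-ratios factor over the 13093 genes above 0 in every library. The deposited FPKM values were made by the authors from those normalized counts with 1 constant per gene, per the file headers and the values. Lengths implied by the FPKM table lay within 1% of the union exon length of GENCODE M21 for 96.8% of 35017 genes. All 54232 genes carry mouse Ensembl identifiers, 54079 have a symbol and 54165 (99.9%) are in GENCODE M21. Coordinates are from GENCODE M21 on GRCm38, counted from 1, and every gene named with coordinates is protein coding. All tests used the raw counts. The normalized and FPKM tables served to check the counts and to derive gene lengths.

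Groups, 15 in all, came from the surgery, transplantation and tissue labels. In Kidney Sham and VFAT scrambled cells the labels give a second library of number 3. In VFAT it differed from its partner by a chi-square per degree of freedom of 18.73, against 57.8 to 187 for 9 other pairs, over 15674 genes (r = 0.988 across genes, against 0.850 to 0.933). In Kidney the value was 9.41, against 3.5 to 14.46 for 14 other pairs, while its correlation with its partner (r = 0.973 across genes) was below that of every other pair (0.979 to 0.992). Each second library was added to library 3 and counted once. Library totals ran from 2803991 to 12986214 counts in Heart, 1241590 to 16912788 in Kidney and 5666563 to 20037187 in VFAT, and 16599 to 24690 genes were detected per library. The share of mitochondrial counts was 8.72 to 21.2% in Heart, 3.78 to 10.21% in Kidney and 3.08 to 9.01% in VFAT. Genes near 1 CPM rest on few counts in the shallowest libraries.

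Each tissue was fitted once over its 5 arms with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, edgeR's expression filter) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison. A gene was called at an adjusted p under 0.05. The 15 comparisons were PNx vs Sham, each cell arm with control or NaKtide cells vs PNx, NaKtide vs scrambled cells and scrambled vs control cells in 3 tissues. PNx vs Sham and NaKtide vs scrambled cells were the main ones. The 3 differences of the PNx effect between tissues were tested as interactions, with libraries of different tissues treated as independent. Log2 CPM values used a prior count of 2, and all p-values are two-sided.

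The 35 gene lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 4 tested members were tested with fry from limma 3.58.1, which asks whether the members move on balance one way and does not compare a list with other genes. Its p-values were adjusted over the lists of a tissue and comparison. The alternative was camera, with an estimated correlation between genes. Lymphocyte markers had too few tested members in every tissue, as had adrenal markers and neutrophils in Kidney and skeletal muscle markers in Heart and Kidney. In a main comparison the named genes are the 6 largest rises and 6 largest falls that passed, with a mean log2 CPM of at least 2 and no predicted-gene name, up to 4 members of each called list, and a fixed set (Src and 5 markers per tissue among it). In the other comparisons they are the 3 largest rises and falls, and in the interactions the 3 genes of lowest adjusted p. Results of 3 genes that the rule names are not reported here. The genes drawn in the plots were picked from these after their values were seen.

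The genes called in PNx vs Sham were tested as 1 signed set with fry in the other arms, with the 200 genes of lowest p where fewer than 20 were called. For comparisons that share PNx libraries, 20 simulations of unchanged groups gave the level without an effect. Splits of the PNx libraries between both sides removed the sharing but kept any effect.

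The alternatives chosen beforehand were DESeq2 1.42.0, limma voom with quality weights, DESeq2's size factors in edgeR, no expression filter, a fit of only the 2 arms compared, a block for the replicate number, other treatments of the second libraries, and leaving out each library in turn. Added after the data were seen were an index of RNA length as a covariate (the mean log2 CPM of the shorter genes minus that of the longer ones, with genes of middle length left out), scores of other tissues as covariates, and a fit without 11 libraries in doubt. A tissue score is the mean log2 CPM of a list, with 0.5 counts added. Shallow libraries weigh less in the count model, and their genes carry larger errors.

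The scripts were tested on counts simulated from the real means and library sizes, with 100 genes changed 4-fold and 100 2-fold. Shared structure of samples was not simulated, so real rates may differ. In PNx vs Sham, 96% and 74% were recovered over 15091 Heart genes, 97% and 58% over 16307 Kidney genes and 87% and 47% over 17552 VFAT genes. In NaKtide vs scrambled cells these were 96% and 72%, 92% and 64%, and 79% and 38%, with 6 to 12 false calls per comparison. A simulated list of unchanged genes had fry p-values of 0.892, 0.505 and 0.946 in PNx vs Sham and 0.597, 0.0166 and 0.0822 in NaKtide vs scrambled cells, in the same order. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.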

Results

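To ask how loss of kidney mass and transplanted cells altered gene expression, RNA was sequenced from the heart, the kidney and visceral adipose tissue (VFAT) of male SCID mice, which lack working T and B lymphocytes, at 12 weeks of age. The 5 arms were sham surgery (Sham), partial nephrectomy (PNx), and PNx followed by transplantation of control cells, of cells carrying NaKtide, a peptide inhibitor of signalling between the Na/K-ATPase and the kinase Src, or of cells carrying a scrambled control. The 76 libraries made 74 samples, with 5 in every group except VFAT scrambled cells, which had 4. Total counts per library ran from 1241590 (Kidney control cells 5) to 20037187 (VFAT control cells 5). The median was 8495773 in Heart (n = 25), 9245410 in Kidney (n = 26) and 7807674 in VFAT (n = 25). Levels are CPM, counts scaled to the TMM-adjusted library total, given as mean ± SD. Log2 fold changes carry their standard error (SE). The labels do not say that the libraries of a group come from separate animals, so p-values measure only the spread between these samples.

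**Figure D1:**
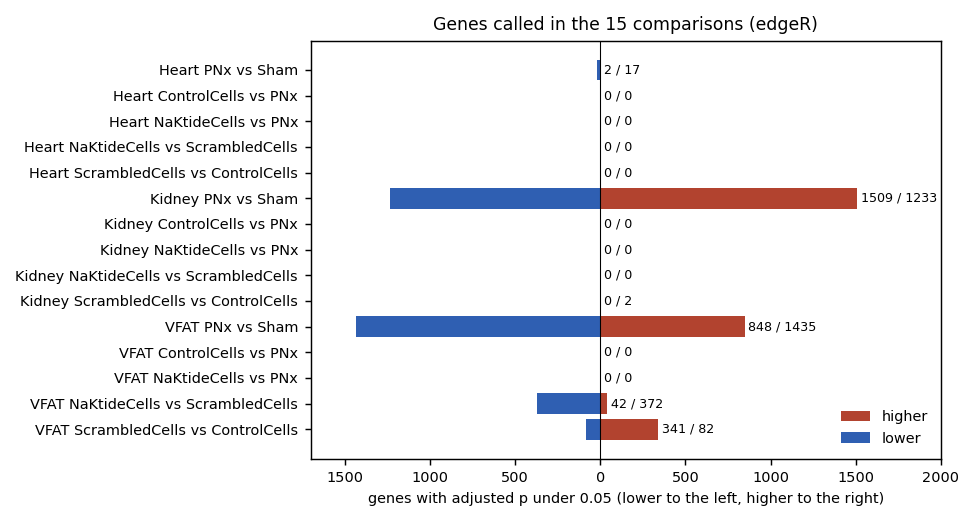
Genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test in 15 comparisons, those higher in the first-named arm to the right of 0 and those lower to the left. Kidney PNx vs Sham (1509 higher, 1233 lower) and VFAT PNx vs Sham (848 higher, 1435 lower) held the largest counts, and 9 comparisons held 0.

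In the heart, Kap, Acsm2, Dnase1, Fxyd2 and Cyp4b1, which the kidney expresses, were lower after PNx than after sham surgery, with the highest levels in 2 Sham libraries, and no gene list was called. Kap (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), a protein of the proximal tubule, measured 9.52 ± 3.28 CPM in PNx and 493 ± 744 CPM in Sham (n = 5 and 5). It was 51.5-fold lower (log2 fold change −5.69, SE 1.05, edgeR adjusted p = 0.0370). Acsm2 (ENSMUSG00000030945, chromosome 7, 119554340 to 119600690), an acyl-CoA synthetase of kidney mitochondria, was 79.4-fold lower (−6.31, SE 1.24, edgeR adjusted p = 0.0370). The nuclease Dnase1 (−5.01), the Na/K-ATPase regulator Fxyd2 (−4.06) and the monooxygenase Cyp4b1 (−3.23) also fell. Trappc9, a trafficking protein, fell by 0.60 on the log2 scale (adjusted p = 0.0422). Vmp1, a membrane protein of autophagy (ENSMUSG00000018171, chromosome 11, 86583865 to 86683836), rose 1.46-fold from 34.1 ± 5.23 to 49.9 ± 2.98 CPM (edgeR adjusted p = 0.0370). The mean of the log2 levels of the proximal tubule list was 5.24 in Heart Sham 2 and 6.87 in Heart Sham 3, against −0.66 to 2.47 in the other Heart libraries. Without both libraries 0 genes were called, and the median change of the 17 falls moved from −5.69 to −1.37.

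Of the heart muscle genes fixed for this comparison, none passed the test. Myh7, the slow myosin heavy chain (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626), measured 3994 ± 711 CPM in PNx and 7455 ± 3097 CPM in Sham (log2 fold change −0.90, SE 0.195, edgeR adjusted p = 0.0601). Myh6, the fast one, measured 13130 ± 2101 and 19740 ± 3948 CPM (−0.59, SE 0.132, adjusted p = 0.0656). Myh7 measured 9952 and 11600 CPM in Sham 2 and 3, highest in proximal tubule genes, and 4952 to 5689 CPM in the other Sham libraries. Without both the values were −0.41 for each gene (adjusted p = 0.759), while leaving out Sham 1, 4 or 5 gave adjusted p of 0.0223, 0.0154 and 0.0131 for Myh7 and 0.0412, 0.0312 and 0.0286 for Myh6. The natriuretic peptide genes Nppa (2.84, SE 1.45, edgeR adjusted p = 0.338) and Nppb (0.62, SE 0.268, adjusted p = 0.262) did not pass. Nppa measured 1.71 without PNx 5, where the atrial gene Myl7 was at 1109 CPM of the plain library total, against at most 175 CPM in the other PNx and Sham hearts. Neither did the collagen gene Col1a1 (1.02, SE 0.562, edgeR adjusted p = 0.372) or Src (−0.38, SE 0.264, edgeR adjusted p = 0.494). Col1a1 measured −0.01 without PNx 1.

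Over 15091 genes, edgeR called 2 rises and 17 falls in Heart PNx vs Sham, with 2387 genes at an unadjusted p under 0.05. DESeq2 called 258 genes and limma voom with quality weights 0. The count was 76 without a filter, 12 with the RNA length index, 1 with only the 2 arms in the fit and 0 with tissue scores. It was 0 without PNx 1, 2, 4 or 5 or Sham 2 or 3, 1 without PNx 3, and 112, 78 and 377 without Sham 1, 4 and 5. Every named call was lost without any single PNx library and without Sham 2 or 3. The adjusted p then ran from 0.0710 to 0.165 for Acsm2, 0.0688 to 0.143 for Kap, Dnase1 and Vmp1, 0.0688 to 0.223 for Fxyd2, and 0.0688 to 0.165 for Cyp4b1 and Trappc9. None of the 24 lists tested in the heart was called by fry. Immediate early genes, with a median log2 fold change of 0.79, had an adjusted p of 0.359 (7 of 12 rose adjusted over the list alone, 0 over all genes). Contractile and calcium handling genes also had 0.359 (5 of 15 fell adjusted over the list alone, 0 over all genes), and the extracellular matrix list 0.546. The cardiac stress list had a fry direction of lower, with a median of 0.13 and a mean of 0.18 (limma fry adjusted p = 0.805).

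**Figure D2:**
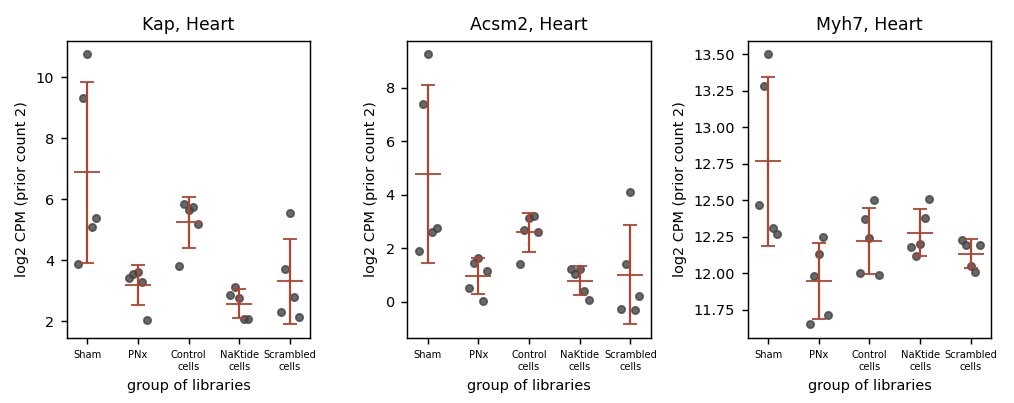
Levels of Kap, Acsm2 and Myh7 in Heart on a log2 CPM scale with a prior count of 2, by arm. Each dot is a library and the red bars are the mean ± SD, and the Sham dots of Kap and Acsm2 lie apart from each other, with group values of 493 ± 744 and 158 ± 261 CPM.

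The arms with cells were compared within the heart to ask what NaKtide changed. Myh7 measured 4991 ± 576 CPM with NaKtide cells and 4504 ± 303 CPM with scrambled cells (n = 5 and 5, log2 fold change 0.15, SE 0.193, edgeR adjusted p = 0.803; 0.08 without NaKtide cells 5). Col1a1 measured 119 ± 39.1 and 232 ± 193 CPM (−0.96, SE 0.557, edgeR adjusted p = 0.721; −0.29 without scrambled cells 3), and Nppa 479 ± 1011 and 403 ± 670 CPM (0.25, SE 1.34, adjusted p = 0.964). Src (0.10), Myh6 (0.02) and Nppb (0.23) did not pass either. The sign turned without 1 library for Nppa (−3.93 without NaKtide cells 5, −0.06 without scrambled cells 2, −0.04 without scrambled cells 5). It also turned for Src (−0.04 without NaKtide cells 5) and Myh6 (−0.002 and −0.02 without NaKtide cells 3 and 5, −0.01 without scrambled cells 3). In NaKtide vs scrambled cells edgeR called 0 genes (903 at an unadjusted p under 0.05, DESeq2 3, voom with quality weights 0). It also called 0 genes in control cells vs PNx (1261, DESeq2 3, voom 0) and NaKtide cells vs PNx (1249, DESeq2 21, voom 572). Scrambled vs control cells also gave 0 in edgeR (1098, DESeq2 0, voom 369), and leaving out control cells 1 gave 1. Fry called 0 of 24 lists in each.

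In the kidney, genes of cell division rose after PNx and genes of the circadian clock moved. Cdk1, the mitotic kinase (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938), rose 3.51-fold, from 1.33 ± 0.364 CPM in Sham to 4.79 ± 0.869 CPM in PNx (n = 5 and 5, log2 fold change 1.81, SE 0.253, edgeR adjusted p = 0.00101). Birc5 rose 4.42-fold (SE 0.315), Mki67, a marker of dividing cells, from 2.89 ± 0.845 to 10.9 ± 3.03 CPM (SE 0.358), and Plk1 by 1.89 (SE 0.326). Of the 13 cell cycle genes tested 11 rose and 0 fell (11 adjusted over the list alone, fry adjusted p = 4.8e-05). The cell cycle list had adjusted p = 0.164 with an estimated correlation. Per2, a repressor of the clock (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324), was 3.98-fold lower at 8.50 ± 3.26 against 33.9 ± 9.29 CPM (−1.99, SE 0.327, edgeR adjusted p = 0.00249). Per3 was 3.58-fold lower (SE 0.297), Nr1d2 2.82-fold lower (SE 0.262) and Hlf 2.03-fold lower (SE 0.196). Of the 16 clock genes 7 fell and 2 rose (9 and 2 adjusted over the list alone, fry adjusted p = 3.1e-05). The clock list had adjusted p = 0.164 with an estimated correlation. None of these gene calls, and neither list call, was lost without any 1 library.

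Genes of detoxification and of growth arrest rose in the same kidneys. Gsta2, a glutathione transferase (ENSMUSG00000057933, chromosome 9, 78331018 to 78355788), rose 4.61-fold from 29.0 ± 6.97 to 134 ± 30.2 CPM (log2 fold change 2.20, SE 0.316, edgeR adjusted p = 0.00101), though it and Gsta1 (2.18, SE 0.407, adjusted p = 0.00492) are near-identical and reads could be split between them. Srxn1 (0.61, SE 0.110, edgeR adjusted p = 0.00376) and Gstm1 (0.76, SE 0.183, adjusted p = 0.0173), both targets of NRF2, also rose. Of the 18 antioxidant and NRF2 target genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, fry adjusted p = 0.00340). The NRF2 list had adjusted p = 0.480 with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose 4.72-fold from 7.25 ± 2.81 to 34.3 ± 23.8 CPM (SE 0.364, edgeR adjusted p = 0.00249), and the stress cytokine Gdf15 from 7.38 ± 3.27 to 17.1 ± 6.40 CPM (SE 0.264, edgeR adjusted p = 0.0122). The death effectors Bax (0.94, SE 0.261) and Bbc3 (0.81, SE 0.226) rose as well, so that 4 of 14 p53 targets rose (5 adjusted over the list alone, fry adjusted p = 0.0391). The p53 list had adjusted p = 0.575 with an estimated correlation. In edgeR, Gstm1 lost its call without Sham 4 (adjusted p = 0.0502), Bax without PNx 3, 4 or 5 or any Sham library (0.0530 to 0.102) and Bbc3 without PNx 3 or 5 or Sham 1, 2, 4 or 5 (0.0531 to 0.106). The p53 list was not called without PNx 1, 2, 3 or 5 or Sham 1, 2, 3 or 4 (0.0546 to 0.119). It had a fry adjusted p of 0.0617 with DESeq2's size factors, 0.157 without a filter and 0.144 with only the 2 arms in the fit, and adjusted p = 0.239 in camera with a preset correlation. The NRF2 list had a fry adjusted p of 0.186 with an index of RNA length as a covariate and 0.201 without the libraries in doubt (PNx 3, 4 and 5 and control cells 4 and 5).

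Transporters of the proximal tubule fell and genes of later nephron segments rose. Slc5a12, a lactate transporter (ENSMUSG00000041644, chromosome 2, 110597298 to 110647779), was 4.96-fold lower in PNx at 66.6 ± 48.1 CPM than in Sham at 331 ± 71.4 CPM (log2 fold change −2.31, SE 0.456, edgeR adjusted p = 0.00754). The amino acid transporters Slc7a13 (−1.12, SE 0.252) and Slc6a19 (−1.06, SE 0.277) and the fatty acid transporter Slc27a2 (−0.79, SE 0.189) fell, as did Slc10a5 (−2.09), Lipo2 (−2.0), Olfm3 (−1.96) and Coq10b (−2.01). Of 16 proximal tubule genes 5 fell and 0 rose (7 fell adjusted over the list alone, fry adjusted p = 0.0391). The proximal tubule list had adjusted p = 0.575 with an estimated correlation. The sodium channel subunit Scnn1b (0.75, SE 0.203), the proton pump subunit Atp6v1g3 (1.07, SE 0.308), the tight junction gene Cldn16 (0.94, SE 0.25) and the calcium binder Calb1 (0.58, SE 0.188) rose. Of 14 genes of the loop of Henle, distal tubule and collecting duct 5 rose (6 adjusted over the list alone, fry adjusted p = 0.00132). These distal genes had adjusted p = 0.166 with an estimated correlation. Calls by edgeR were lost without PNx 3 for Slc10a5 (adjusted p = 0.0615), Olfm3 (0.0525), Slc6a19 (0.0810), Scnn1b (log2 fold change 0.47, 0.123), Atp6v1g3 (0.66, 0.150), Cldn16 (0.112) and Calb1 (0.0739). Other single libraries ended those of Slc27a2 (Sham 4, 0.0511), Slc6a19 (Sham 2 or 4), Scnn1b (Sham 1, 3 or 4), Cldn16 (Sham 1, 2, 3 or 4), Atp6v1g3 (PNx 5 or any Sham) and Calb1 (PNx 1 or 5 or any Sham), with adjusted p from 0.0516 up for Scnn1b, 0.0530 for Cldn16, 0.0544 for Atp6v1g3 and 0.0566 for Calb1. The proximal tubule list was not called without PNx 3 or any Sham library (fry adjusted p from 0.0550 to 0.0913), nor with the RNA length index as a covariate (0.114), without the libraries in doubt (0.201) or with only the 2 arms in the fit (0.144). The distal list had a fry adjusted p of 0.0615 with only the 2 arms in the fit.

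The largest rises in the kidney rested on Kidney PNx 3. Lcn2, an iron-binding protein of injured tubules and neutrophils (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose 74.3-fold from 3.19 ± 1.42 to 238 ± 502 CPM (log2 fold change 6.22, SE 1.41, edgeR adjusted p = 0.0141), but without PNx 3, at 1137 CPM, it measured 2.04 (adjusted p = 0.171). The same library ended the edgeR calls of the leukocyte genes Rac2 (3.29 with it; 0.53, adjusted p = 0.425 without), Coro1a (3.24; 0.88, 0.234), Lyz2 (3.1; 1.51, 0.113) and its near copy Lyz1 (3.42; 1.81, 0.107), whose shared reads leave the last pair uncertain. Rac2 was also lost without Sham 1 or 4 (adjusted p from 0.0511) and Coro1a without Sham 4 (0.0521). Gc, the vitamin D binding protein, rose from 6.11 ± 1.19 to 60.0 ± 62.3 CPM (3.29, SE 0.540, edgeR adjusted p = 0.00249) and kept its call without any 1 library. Src measured 0.18 (SE 0.117, edgeR adjusted p = 0.237) and Col1a1 27.4 ± 15.8 and 11.8 ± 2.75 CPM in PNx and Sham (1.21, SE 0.452, adjusted p = 0.0589; 1.32 and 0.0360 without PNx 1). The injury marker Havcr1 (−0.32, SE 0.268, edgeR adjusted p = 0.352), the phosphate transporter Slc34a1 (−0.43) and the loop protein Umod (0.23) did not pass. Macrophage markers had 7 of 11 rises with a fry adjusted p of 0.139, and tubule injury genes 4 of 13 with 0.0503. The Na/K-ATPase and Src list had a fry direction of lower with a median of 0.15 and a mean of 0.26 (limma fry adjusted p = 0.579).

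Over 16307 genes, edgeR called 1509 rises and 1233 falls in Kidney PNx vs Sham, 2742 in all (6885 at an unadjusted p under 0.05, DESeq2 4486, voom with quality weights 7232). With DESeq2's size factors the balance turned, to 1260 rises and 1429 falls (46.9% rises against 55%). The difference in mean log2 level between short and long genes was −0.80 and −0.89 in PNx 1 and 2 and 0.19, 0.06 and 0.20 in PNx 3, 4 and 5, against −0.91 to −0.75 in Sham. The count was 146 with only the 2 arms in the fit, 1007 without a filter and 4283 with the second Sham library of number 3 kept separate. With the length index as a covariate 546 genes were called, and 97 without PNx 3, 4 and 5 and control cells 4 and 5. The count was 5768, 6534, 307, 719 and 933 without PNx 1 to 5 in turn, and 706, 647, 704, 384 and 1116 without Sham 1 to 5.

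**Figure D3:**
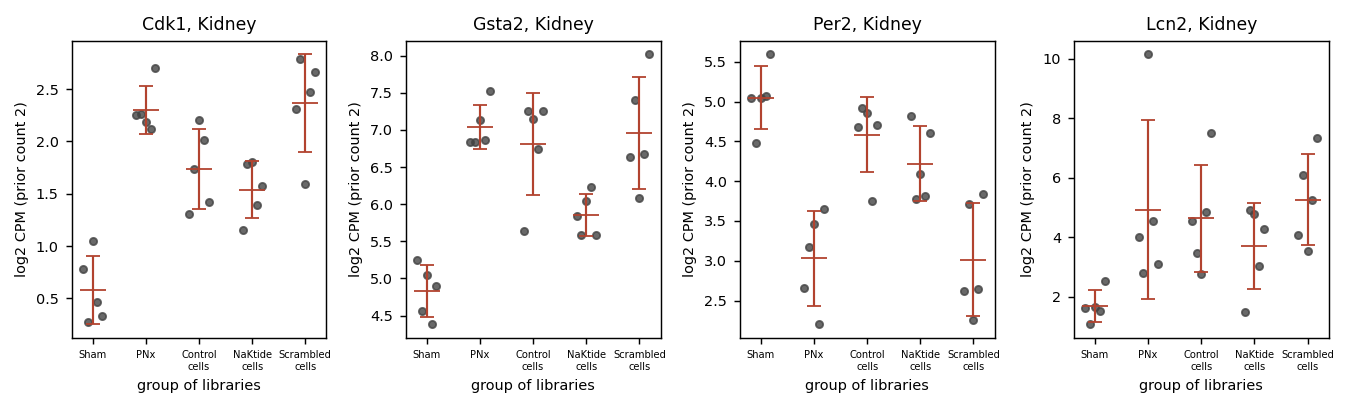
Levels of Cdk1, Gsta2, Per2 and Lcn2 in Kidney on a log2 CPM scale with a prior count of 2, by arm. Each dot is a library and the red bars are the mean ± SD, and the single highest Lcn2 dot in PNx is the library at 1137 CPM.

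In the kidneys of mice with cells, clock genes stood higher with NaKtide cells than with scrambled cells as a list, although none passed alone over all genes. Per2 measured 19.3 ± 6.46 CPM with NaKtide cells and 8.73 ± 4.45 CPM with scrambled cells (n = 5 and 5, log2 fold change 1.14, SE 0.320, edgeR adjusted p = 0.754), Per3 18.7 ± 8.03 and 8.58 ± 3.27 CPM (1.12, SE 0.292, adjusted p = 0.593), and Hlf 108 ± 12.4 and 63.5 ± 11.1 CPM (0.76, SE 0.196, adjusted p = 0.591). Of the 16 clock genes 13 were higher, and 3 passed adjusted over the list alone (fry adjusted p = 0.00793). The clock list here had adjusted p = 0.0360 with an estimated correlation. Relative to PNx without cells, the clock list was called higher with control cells (fry adjusted p = 0.00508, and adjusted p = 0.0428 with an estimated correlation). There 8 clock genes rose and 3 fell adjusted over the list alone. With NaKtide cells it was also called higher (4 rose adjusted over the list alone, fry adjusted p = 0.0209), but had adjusted p = 0.458 with an estimated correlation. It was lower with scrambled than with control cells (fry adjusted p = 0.00249, 9 fell and 3 rose adjusted over the list alone). This decrease had adjusted p = 0.0217 with an estimated correlation. The cell cycle list was lower with NaKtide cells than in PNx (12 of 13 lower, 8 falls adjusted over the list alone, fry adjusted p = 0.0238). The cell cycle genes had adjusted p = 0.458 with an estimated correlation. The p53 list was higher with scrambled than with control cells (4 rises and 1 fall adjusted over the list alone, fry adjusted p = 0.0127). The p53 genes had adjusted p = 0.0426 with an estimated correlation. In NaKtide cells vs PNx the clock call was lost without NaKtide cells 1 (0.0555) or PNx 1 or 3 (0.0561), and the cell cycle call without NaKtide cells 1 or PNx 1, 2, 3 or 5 (0.0514 to 0.0629). The p53 call was lost without control cells 3 (0.0656), control cells 4 (0.0880) or scrambled cells 5 (0.0568). With only the 2 arms in the fit the clock list had fry adjusted p of 0.110 in NaKtide vs scrambled cells and 0.102 in scrambled vs control cells. Without the libraries in doubt it had 0.0764 in control cells vs PNx and 0.228 in NaKtide cells vs PNx, where it had 0.0696 with the RNA length index. The cell cycle list in NaKtide cells vs PNx had 0.204 without the libraries in doubt and 0.0937 without a filter, and the p53 list in scrambled vs control cells 0.0561 without the libraries in doubt.

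Rasd2, a small GTPase (ENSMUSG00000034472, chromosome 8, 75213944 to 75224113), fell from 9.47 ± 2.19 CPM with control cells to 3.54 ± 1.18 CPM with scrambled cells (n = 5 and 5, log2 fold change −1.44, SE 0.220, edgeR adjusted p = 0.0149). Tgm1, a transglutaminase, fell from 76.2 ± 16.7 to 33.6 ± 9.44 CPM (−1.18, SE 0.204, edgeR adjusted p = 0.0452). Rasd2 lost its call without control cells 2 or 3 or scrambled cells 3 (0.0705 to 0.119), and Tgm1 without control cells 2, 3, 4 or 5 or scrambled cells 2, 3, 4 or 5 (0.0519 to 0.188). These 2 genes alone were called in scrambled vs control cells (1753 at an unadjusted p under 0.05, DESeq2 89, voom with quality weights 1489), and the count was 0 without control cells 2 or 3 or scrambled cells 3 and 1 without control cells 4 or 5 or scrambled cells 2. It was 209 with the RNA length index, 228 without PNx 3, 4 and 5 and control cells 4 and 5, 1 without a filter and 0 with only the 2 arms in the fit. In NaKtide vs scrambled cells, Lcn2 measured −1.75 (SE 1.14, edgeR adjusted p = 0.879), Havcr1 −0.70 (SE 0.266, adjusted p = 0.876), Src 0.01, Umod −0.20, Slc34a1 0.36, Cry2 0.49 and Col1a1 −0.11. Without scrambled cells 5 Lcn2 measured −0.92, Havcr1 −0.35, Umod −0.04 and Slc34a1 0.20, and without NaKtide cells 1 Umod −0.09, Slc34a1 0.22 and Cry2 0.30. Src turned to −0.003, −0.01 and −0.01 without NaKtide cells 2, 4 and 5 and −0.02 and −0.04 without scrambled cells 3 and 5, and Col1a1 to 0.11, 0.08 and 0.28 without NaKtide cells 1 and 4 and scrambled cells 2. There edgeR called 0 genes (819 at an unadjusted p under 0.05, DESeq2 14, voom 4401, 2 without the libraries in doubt), and it called 0 in control cells vs PNx (1049, DESeq2 20, voom 2088, 18 with the length index) and in NaKtide cells vs PNx (3116, DESeq2 0, voom 6773).

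The genes changed by PNx were then followed as a signed set into the arms with cells. In Kidney, 2366 of the 2742 genes (86.3%) had the opposite sign in NaKtide vs scrambled cells, a comparison that shares no library with the one that chose them, with a fry p of 0.200. It was 0.00245 without Kidney PNx 3 and 0.0335 without Kidney Sham 4, 0.0140 with the 200 genes of lowest p as the set, and 0.0316 with the RNA length index as a covariate. In Heart 105 of 200 genes (52.5%, fry p of 0.731) and in VFAT 1188 of 2283 (52.0%, fry p of 0.942) had the opposite sign. With the set chosen anew in each fit, the share in Heart ran from 19.7% without a filter to 74% with tissue scores as covariates, which gave 18% in VFAT. The direction of the set turned in Heart without scrambled cells 3 (fry p of 0.895) or Sham 1, 2 or 4 (0.970, 0.964, 0.983), and in VFAT without NaKtide cells 1 (0.789), PNx 1 (0.974), scrambled cells 2 or 4 (0.997, 0.918) or Sham 2 or 3 (0.860, 0.933).

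Against PNx without cells, which shares its PNx libraries with the comparison that chose the genes, 2728 of 2742 Kidney genes (99.5%) were opposite with NaKtide cells (fry p of 0.00736) and 2581 (94.1%) with control cells (fry p of 0.0512). Across all genes tested, mean log2 CPM differences of NaKtide cells vs PNx correlated with those of PNx vs Sham (r = −0.881, covariance −0.285). In 20 simulations of unchanged groups r was −0.437 (−0.0502), but these drew genes independently and simulated Sham, PNx and control-cell libraries only. With the PNx libraries split between both sides in 10 ways, r averaged −0.552 (−0.199) and ran from −0.682 to 0.0265. For control cells r was −0.477 (−0.115) observed and −0.150 (−0.0293) split. Every r is across all genes tested, which are not independent replicates. In Heart the set had fry p of 0.0564 with control cells (183 of 200 opposite; r −0.347 observed, −0.489 simulated, −0.002 split) and 0.0837 with NaKtide cells (150 of 200; −0.288, −0.489, 0.0562). In VFAT it had 0.517 (1589 of 2283; r −0.194, −0.496, 0.0417) and 0.587 (1563 of 2283; −0.235, −0.496, −0.004).

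In visceral fat, transcripts of the epididymis and of the protein-folding machinery were lower after PNx. Gpx5, a secreted peroxidase of the epididymis (ENSMUSG00000004344, chromosome 13, 21286429 to 21292731), was 468-fold lower, at 16.9 ± 33.3 CPM in PNx against 8022 ± 5684 CPM in Sham (n = 5 and 5, log2 fold change −8.87, SE 1.56, edgeR adjusted p = 0.000878). PNx 2 held 76.5 CPM against 0.329 to 3.94 CPM in the other PNx libraries, and without it the value was −11.91. Adam7 measured 4.80 ± 9.57 and 3899 ± 3317 CPM (SE 1.5, edgeR adjusted p = 0.000288), and Lcn9 (−9.80), Lcn5 (−9.07), Rnase10 (−9.66), Cst11 (−9.62) and Teddm2 (−8.89), likewise epididymal, fell with them on the log2 scale. Of 13 epididymis and accessory gland genes 10 fell and 0 rose (10 adjusted over the list alone, fry adjusted p = 0.0169). The epididymis list had adjusted p = 0.424 with an estimated correlation. Their mean log2 level was 6.78, 1.90, 5.80, 8.40 and 7.72 in Sham 1 to 5 and at most 1.12 in every other VFAT library. Sdf2l1, a component of the endoplasmic reticulum (ENSMUSG00000022769, chromosome 16, 17130138 to 17132383), was 12.7-fold lower, at 7.96 ± 1.68 against 101 ± 73.8 CPM (SE 0.622, edgeR adjusted p = 0.000645), and Manf (−2.39, SE 0.422), Pdia4 (−1.96, SE 0.331) and Pdia6 (−1.91, SE 0.324) fell with it. In Sham 2, the Sham library with the lowest epididymis score, Sdf2l1 measured 5.26 CPM and Manf 41.0 CPM, against 72.2 to 178 and 223 to 479 CPM in the other Sham libraries. Of 15 genes of the unfolded protein and integrated stress response 9 fell and 2 rose (9 and 2 adjusted over the list alone, fry adjusted p = 0.0346). The unfolded protein list had adjusted p = 0.424 with an estimated correlation. Of 13 cell cycle genes 5 fell, among them Cdk1 (−1.27, SE 0.296), Top2a (−1.79), Mki67 (−1.93) and Rrm2 (−1.21), and 10 adjusted over the list alone (fry adjusted p = 0.0360). Cell cycle genes here had adjusted p = 0.424 with an estimated correlation.

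Genes of vessels and macrophages, and the adipocyte gene Cfd, were higher in the same comparison. Adipoq measured 229 and 437 CPM in Sham 4 and 1, with epididymis scores of 8.40 and 6.78, and 2428 CPM in Sham 2, with a score of 1.90, against 2072 to 2649 CPM in PNx, and Esam 17.5, 22.0 and 50.5 CPM in Sham 4, 1 and 2. Esam, an endothelial adhesion molecule (ENSMUSG00000001946, chromosome 9, 37528078 to 37538319), rose 2.14-fold from 32.4 ± 13.1 to 69.5 ± 12.6 CPM (log2 fold change 1.10, SE 0.251, edgeR adjusted p = 0.00642), with Tie1 (0.96), Emcn (0.88) and Pecam1 (1.01). Of 10 endothelial genes 6 rose (9 adjusted over the list alone, fry adjusted p = 0.0169). The endothelial list had adjusted p = 0.424 with an estimated correlation. The complement gene C1qa rose 2.39-fold from 50.2 ± 12.3 to 120 ± 34.2 CPM (SE 0.281, edgeR adjusted p = 0.00564), with C1qb (1.19), C1qc (1.18) and Csf1r (1.09), so that 5 of 12 macrophage genes rose (7 adjusted over the list alone, fry adjusted p = 0.0269). The macrophage list had adjusted p = 0.424 with an estimated correlation. Cfd, the adipocyte protein adipsin (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), rose 3.07-fold from 1650 ± 1217 to 5061 ± 654 CPM (SE 0.382, edgeR adjusted p = 0.00799), the 1 riser among 14 adipocyte identity genes (1 adjusted over the list alone, fry adjusted p = 0.0458). The adipocyte list had adjusted p = 0.424 with an estimated correlation. Agt, the angiotensin precursor, rose 4.12-fold (SE 0.410, edgeR adjusted p = 0.00250), the 1 riser among 10 adipokine genes (4 adjusted over the list alone, fry adjusted p = 0.0185). The adipokine list had adjusted p = 0.424 with an estimated correlation. Adipoq, which encodes adiponectin, measured 2401 ± 222 and 1119 ± 879 CPM (1.10, SE 0.409, edgeR adjusted p = 0.0784), Fabp4 0.70, Retn 0.85, Rbp4 1.15 and Rarres2 1.24. Without Sham 2 these 5 genes had adjusted p of 0.00500, 0.0207, 0.0233, 0.00917 and 0.00833, and Rarres2 0.0474 without PNx 1.

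Fxyd2, the pump's regulatory subunit (ENSMUSG00000059412, chromosome 9, 45399669 to 45410278), rose in VFAT from 6.11 ± 2.41 to 18.8 ± 15.7 CPM (log2 fold change 1.61, SE 0.534, edgeR adjusted p = 0.0489), the 1 riser among 12 genes of the Na/K-ATPase and Src list (3 adjusted over the list alone, fry adjusted p = 0.0360). That list had adjusted p = 0.424 with an estimated correlation and 0.0742 with a preset one. Src measured −0.61 (SE 0.295, edgeR adjusted p = 0.190), Atp1a4 1.22 (adjusted p = 0.0540), Fxyd5 1.06 (0.0632) and Fxyd1 0.87. Ucp1, the heat-producing protein of brown fat (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), was 101-fold lower, at 0.564 ± 0.623 against 57.1 ± 58.8 CPM (−6.65, SE 1.41, edgeR adjusted p = 0.00389), while Ppargc1a (0.20), Lep (0.09) and Ccl2 (0.15) did not pass. The largest rises were Cyp2f2 (9.01-fold; 8.33 ± 6.04 to 74.8 ± 21.8 CPM), the estrogen sulfotransferase Sult1e1 (7.79-fold; 4.90 ± 2.24 to 37.9 ± 3.83 CPM), Prtn3 (2.88), Cish (2.67), Plppr3 (2.66) and Cldn24 (2.46). Myh4, a muscle myosin, averaged 0.485 ± 0.607 CPM in PNx and 618 ± 1367 CPM in Sham, where it rested on Sham 3 (log2 fold change −10.23, edgeR adjusted p = 0.00821, against −3.64 and 0.117 without it). Ceacam10 fell by 9.87 (SE 2.95, edgeR adjusted p = 0.0309), and lost its call without any PNx library and without Sham 1 or 4 (0.0566 to 0.0732). Fxyd2 lost its call without PNx 1 or 2 or Sham 1, 2, 4 or 5 (0.0548 to 0.207; 0.98 without PNx 2). Atp1a4 passed without Sham 2 (0.0191) or 3 (0.0379) and Fxyd5 without Sham 2 (0.0248), and without Sham 1 or 4 the sign of Lep (−0.15, −0.17) turned, as did those of Ccl2 (−0.13) without Sham 1 and Ppargc1a (−0.04) without PNx 1.

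Over 17552 genes, edgeR called 848 rises and 1435 falls in VFAT PNx vs Sham, 2283 in all (4780 at an unadjusted p under 0.05, DESeq2 3078, voom with quality weights 4647). With scores of epididymal, pancreatic and muscle genes as covariates 0 genes and 0 of these lists were called. The count was 957 without the libraries in doubt (Sham 1 and 4, scrambled cells 2 and 4), with Sham 3 and 5 kept. It was 384 with only the 2 arms in the fit, 3608 with the RNA length index and 1492 without PNx 5. It was 1137, 4057 and 1089 without Sham 1, 2 and 4. Single libraries ended the calls of Top2a (Sham 4 or 5, 0.0520 and 0.0706), Mki67 (PNx 2, 3 or 4 or Sham 1, 4 or 5, 0.0570 to 0.126), Rrm2 (PNx 2 or 3 or Sham 4 or 5, 0.0635 to 0.111), Emcn (Sham 4, 0.0513), Pecam1 (PNx 5 or Sham 1 or 4, 0.0524 to 0.0728), C1qb (PNx 2 or 4 or Sham 1 or 4, 0.0510 to 0.0729) and Csf1r (PNx 2, 3, 4 or 5 or Sham 1, 3, 4 or 5, 0.0577 to 0.132). Among the lists, the endothelial one kept its call without any 1 library, and the epididymis one was lost without PNx 2 (0.0651) and the adipokines without Sham 1 (0.0626) or 4 (0.0645). Without PNx 1, 2, 4 and 5 and Sham 1 and 4 in turn, the Na/K-ATPase and Src list had adjusted p of 0.0668, 0.0868, 0.0503, 0.0503, 0.109 and 0.116, and the unfolded protein list 0.0668, 0.0580, 0.0503, 0.0503, 0.0926 and 0.116. The cell cycle list was lost without any PNx library (0.0503 to 0.0805) and without Sham 1 (0.0694), 4 (0.116) or 5 (0.0855), the adipocyte list without any PNx library (0.0656 to 0.0826) and without Sham 1 (0.159) or 4 (0.117), and the macrophage list without PNx 4 or 5 (0.0503) or Sham 1 (0.0694) or 4 (0.0857). With only the 2 arms in the fit the endothelial list had a fry adjusted p of 0.0592, the Na/K-ATPase and Src list 0.172, the unfolded protein list 0.161, the cell cycle list 0.138, the adipocyte list 0.215 and the adipokines 0.126. Without the libraries in doubt the last 5 had 0.265, 0.230, 0.150, 0.464 and 0.151. The adipocyte list had 0.0545 with the RNA length index.

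**Figure D4:**
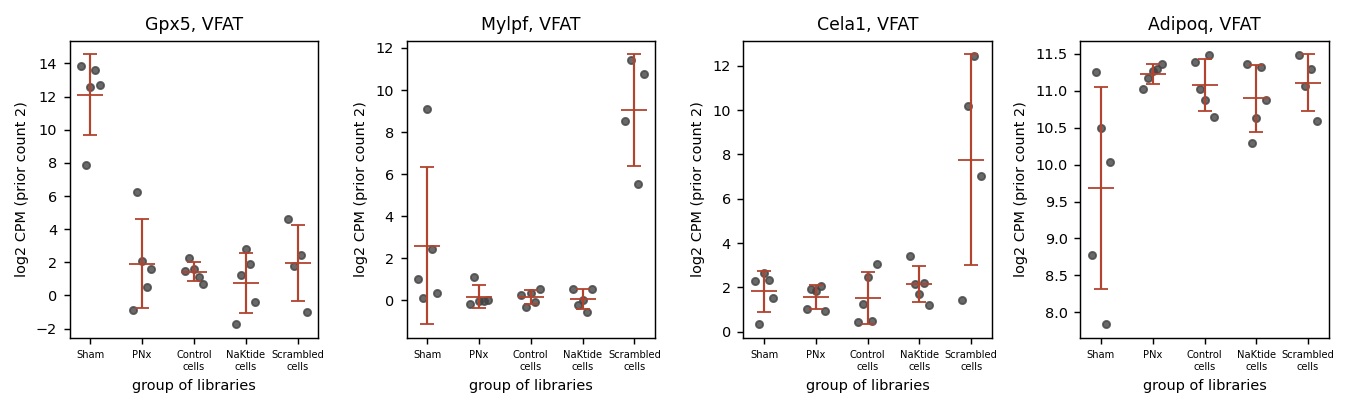
Levels of Gpx5, Mylpf, Cela1 and Adipoq in VFAT on a log2 CPM scale with a prior count of 2, by arm. Each dot is a library and the red bars are the mean ± SD, with Gpx5 highest in Sham and Mylpf and Cela1 highest with scrambled cells.

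In visceral fat, transcripts of skeletal muscle and pancreas were far higher with scrambled than with NaKtide cells. Mylpf, a light chain of fast muscle (ENSMUSG00000030672, chromosome 7, 127208890 to 127214298), measured 0.872 ± 0.352 CPM with NaKtide cells (n = 5) and 1214 ± 1240 CPM with scrambled cells (n = 4; log2 fold change −10.40, SE 1.81, edgeR adjusted p = 0.00780). Myh4 averaged 0.879 ± 1.47 and 6024 ± 6632 CPM (SE 2.58, edgeR adjusted p = 0.00951), and Myh1, a related myosin of the same gene cluster, also fell (−13.38). So did Tnni2 (−10.67), Myoz1 (−10.62), Actn3 (−8.39), Pygm (−7.86) and Casq1 (−7.05). All 9 muscle genes fell (9 adjusted over the list alone, fry adjusted p = 0.0275), and their mean log2 level was 7.86, 11.10, 4.75 and 10.52 in scrambled cells 1 to 4. The muscle list had adjusted p = 0.391 with an estimated correlation. Cela1, a pancreatic elastase (ENSMUSG00000023031, chromosome 15, 100674421 to 100687921), was 348-fold lower, at 4.83 ± 3.22 against 1692 ± 2587 CPM (−8.44, SE 1.29, edgeR adjusted p = 0.00213). All 6 pancreas genes fell over all genes tested, with a fry adjusted p of 0.208 for the list.

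Sfrp5, a secreted inhibitor of Wnt signalling made in fat (ENSMUSG00000018822, chromosome 19, 42197971 to 42202252), rose 14.8-fold with NaKtide cells, from 4.95 ± 2.16 to 72.9 ± 38.2 CPM (log2 fold change 3.88, SE 0.825, edgeR adjusted p = 0.0132). Folh1 (3.23), Col4a4 (3.11), Cetn4 (2.36) and Dzank1 (2.31) rose as well. NaKtide cells 2 and 3 had a mean log2 level of the proximal tubule list of 4.35 and 2.98, against −1.83 to 1.23 with scrambled cells, and Slc34a1, a phosphate transporter of that segment, at 45.9 and 17.5 CPM of the plain library total (at most 5.43 with scrambled cells). Among the libraries compared, both had the highest levels of each of these 4 genes, with Folh1 at 27.9 and 20.7 CPM against 3.72 to 9.25 CPM in the other NaKtide libraries. Src measured 29.1 ± 7.78 and 15.6 ± 5.17 CPM (0.90, SE 0.317, edgeR adjusted p = 0.109). Adipoq measured 1983 ± 605 and 2266 ± 570 CPM (−0.19, SE 0.428, edgeR adjusted p = 0.885), Ucp1 −4.0 (SE 1.26, adjusted p = 0.0871; −5.80 and 0.0497 without NaKtide cells 5), Lep 0.98, Ccl2 −1.98 and Ppargc1a −0.02. Without scrambled cells 4 Ccl2 measured 0.85, and Ppargc1a turned positive without NaKtide cells 1, 4 or 5 (0.23, 0.04, 0.09) or scrambled cells 2 or 4 (0.12, 0.52).

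Over 17552 genes, edgeR called 42 rises and 372 falls here, 414 in all (3412 at an unadjusted p under 0.05, DESeq2 1589, voom 841). It called 0 with tissue scores and 15 without the libraries in doubt, with scrambled cells 1 and 3 kept. It called 65 with only the 2 arms in the fit and 946 with the RNA length index. The count was 159, 147, 202 and 242 without NaKtide cells 2, 3, 4 and 5, and 740, 259, 676 and 155 without scrambled cells 1 to 4. Calls were lost for Sfrp5 without scrambled cells 4 (0.0727), Actn3 without NaKtide cells 3 (0.0563) and Casq1 without NaKtide cells 2, 3, 4 or 5 or scrambled cells 2 (0.0528 to 0.0731). NaKtide cells 2, 3, 4 or 5 and scrambled cells 2 or 4 also ended those of Folh1 (0.0508 to 0.155), Col4a4 (0.0546 to 0.186), Cetn4 (0.0569 to 0.177) and Dzank1 (0.0619 to 0.186), with scrambled cells 1 doing so for Folh1 and Cetn4 and scrambled cells 3 for Col4a4 and Dzank1. The muscle list was lost without NaKtide cells 1 (0.118), 2 (0.0992), 3 (0.0765) or 5 (0.108), with the second library of number 3 kept separate (0.0976) and without the libraries in doubt (0.12).

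With scrambled against control cells in visceral fat, Mylpf rose by 10.33 on the log2 scale (SE 1.81, edgeR adjusted p = 0.00885), Myh4 by 12.53 (SE 2.57, adjusted p = 0.0120) and Actn3 by 9.49 (SE 1.87, adjusted p = 0.00962), and all 9 muscle genes rose (n = 4 and 5; 9 adjusted over the list alone, fry adjusted p = 0.0325). The muscle genes had adjusted p = 0.213 with an estimated correlation. Apoa1, a lipoprotein of the liver (ENSMUSG00000032083, chromosome 9, 46228580 to 46230466), fell from 400 ± 577 to 0.867 ± 0.626 CPM (SE 2.21, edgeR adjusted p = 0.0405), with Serpina1b (−7.90, SE 2.11, adjusted p = 0.0486), whose near-identical family members make it uncertain. Both calls were lost without control cells 3 or 5 or any scrambled-cell library (0.0669 to 0.177 for Apoa1, 0.0847 to 0.193 for Serpina1b), and the muscle list without any control-cell library (0.0522 to 0.175) or scrambled cells 4 (0.0534). That list had a fry adjusted p of 0.148 with the second library of number 3 kept separate and 0.0519 with it left out, 0.119 with only the 2 arms in the fit, 0.0650 with the RNA length index, 0.372 without the libraries in doubt and 0.938 with tissue scores. In all edgeR called 341 rises and 82 falls, 423 genes (2759 at an unadjusted p under 0.05, DESeq2 1094, voom 0), 0 with tissue scores, 13 without the libraries in doubt, 45 with only the 2 arms in the fit, and 147, 129, 647, 220 and 135 without control cells 3 and 5 and scrambled cells 1, 2 and 4. Against PNx without cells edgeR called 0 genes with control cells (442 at an unadjusted p under 0.05, DESeq2 21, voom 39) and 0 with NaKtide cells (652, DESeq2 28, voom 3795).

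The effect of PNx was tested for differences between tissues over 17389 genes, in libraries that included Heart Sham 2 and 3, with proximal tubule scores of 5.24 and 6.87, and VFAT Sham 1, 3, 4 and 5, with epididymis scores of 5.80 to 8.40. In Kidney minus Heart, Coq10b (ENSMUSG00000025981, chromosome 1, 55052770 to 55072702), a coenzyme Q binding protein, differed by −2.17 (SE 0.388), the hydrolase Adprhl2 by 1.49 (SE 0.266) and the protease Mmp15 by 1.72 (SE 0.286), each with an edgeR adjusted p of 0.0220, and 17 genes were called, 9 higher and 8 lower (52.9% higher; 5082 at an unadjusted p under 0.05, DESeq2 2287). With DESeq2's size factors 718 genes were called, 601 higher and 117 lower (83.7% higher). All 3 named calls were lost without Heart PNx 2, Heart Sham 3 or Kidney PNx 4 (0.0509 to 0.0551), where the count was 0. It was 1115, 1243 and 2101 without Heart Sham 1, 4 and 5, 2794, 3143, 6 and 7 without Kidney PNx 1, 2, 3 and 5, and 9, 10, 6, 10 and 11 without Kidney Sham 1 to 5. In VFAT minus Heart, the potassium channel Kcnj11 (−6.49, SE 0.962), the amino acid transporter Slc7a5 (−6.43, SE 0.919) and Asap3 (1.85, SE 0.253) had an adjusted p of 0.00055 among 841 called genes (301 higher, 540 lower; 3780 at an unadjusted p under 0.05, DESeq2 1539), and the count was 469 without Heart Sham 2 and 457, 2182 and 452 without VFAT Sham 1, 2 and 4. In VFAT minus Kidney, Spink8 (−10.82, SE 1.32; adjusted p = 8.0e-05), the chaperone Clu (−6.56, SE 0.858; 0.000116) and the ribosomal protein Rpl3l (−8.71, SE 1.21; 0.000189) led 1131 called genes (287 higher, 844 lower; 4244 at an unadjusted p under 0.05, DESeq2 1708), and the count was 2375 without VFAT PNx 2, 2880 without VFAT Sham 2 and 746 without VFAT Sham 4. Without the libraries in doubt the 3 counts were 0, 183 and 208. Without a filter 8 and 544 genes were called in the first 2, and 1341 in the first with the second libraries kept separate.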

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

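The fits with covariates were chosen after marker levels and principal components had been seen, and the test of a heart response without Heart Sham 2 and 3 and the shuffling of covariates within arms only after the results were seen.

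In the heart, 17 genes, among them genes of the nephron, were lower after PNx, and Heart Sham 2 and 3 had the highest scores of the proximal tubule list. Kidney RNA in the Sham libraries is a candidate source: across 116 genes abundant in Kidney Sham and scarce in hearts with NaKtide cells, the excess of Heart Sham over Heart PNx tracked the Kidney Sham level at r = 0.84 (across genes, which are not independent replicates), with a median share of 2.43% (quartiles 2.07 and 2.83%) and 112 genes above 0. Without Sham 2 and 3, 0 of the 17 falls were called by edgeR and their median moved from −5.69 to −1.37 (median SE 0.604), with 17 of 17 still lower, but these libraries were left out for their high levels of such genes, so this decides nothing about a response of the heart, which stays open. As many genes as the real 19 were called in 13 of 100 splits of the same libraries, so chance cannot be excluded. The highest other split called 2246 genes, which points to a structure of the samples.

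In visceral fat, edgeR called 2283 genes in PNx vs Sham and 414 in NaKtide vs scrambled cells, while transcripts of the epididymis were high in Sham and those of muscle and pancreas with scrambled cells. With the RNA length index as a covariate 2244 of 2283 genes stayed called in the same direction. Shuffled indices kept 1911 to 2264, so RNA length stays open. With the tissue scores as covariates 0 of 2283 and 0 of 414 stayed called, the median absolute log2 fold change going from 1.42 to 0.598 (SE 0.366 to 0.681) and from 3.09 to 0.972 (SE 0.724 to 1.22). Arm alone set a share of 0.726 to 0.782 of the variance of the scores, and scores shuffled within arms kept as few genes in 9 and 12 of 40 shuffles, so tissue of other organs and an effect of the arm cannot be told apart. The adipocyte list, higher after PNx with a fry p of 0.0141, had a fry p of 0.641 in the lower direction with the scores, which leaves a change in adipocytes open as well.

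In the kidney, edgeR called 2742 genes in PNx vs Sham, and PNx 3, 4 and 5 had another balance of short and long genes than PNx 1 and 2. With the length index as a covariate 421 of these genes stayed called in the same direction (median absolute log2 fold change 0.891 to 0.475, SE 0.26 to 0.189), but 18 of 40 shuffles within arms kept as few, so RNA length or integrity and an effect of PNx cannot be told apart. Whether the count rests on PNx 3, 4 and 5 together stays open: leaving them out gave 2 genes against a median of 461.5 over the 10 ways to leave out 3 PNx libraries, but so did leaving out 1, 3 and 5, leaving out 4 and 5 while keeping 3 gave 908 and 1569, leaving out 3 with 1 or 2 but not both gave 2 to 15, and leaving out 1 and 2 with another gave 6463 to 8402. A shift in the time of day may underlie the clock genes, of which 5 of 9 called had the same sign in both Heart and VFAT (7 in Heart, 6 in VFAT), too few to decide. Of 100 splits 1, the real one, called as many genes and the highest other called 0, so by called genes chance alone is unlikely. Another split reached 6139 genes at an unadjusted p under 0.05 against 6885.

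For each remaining comparison 100 splits of the libraries were counted. In VFAT PNx vs Sham 2 splits called at least the real 2283 genes, in NaKtide vs scrambled cells 2 the real 414. In VFAT scrambled vs control cells 1 called the real 423. The highest others called 2843, 1717 and 399, so chance is not excluded. At an unadjusted p under 0.05, 3, 5 and 1 splits reached the real 4780, 3412 and 2759. In Kidney scrambled vs control cells 2 splits called at least the real 2 genes (highest other 1277), but 20 reached the real 1753 genes at an unadjusted p under 0.05 (highest other 4693), so chance stays open there. Splits calling several times the real count, 1717 and 1277 here, point to a structure of the samples.

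Where edgeR called 0 genes, all 100 splits are as large by construction, and that count says nothing about chance. Given instead, after the number called in the highest other split, are the real count at an unadjusted p under 0.05, the highest other and the number of splits reaching the real one. In Heart these were 0, with 1261, 3057 and 16, in control cells vs PNx (DESeq2 3, voom 0), 677, with 1249, 4430 and 21, in NaKtide cells vs PNx (DESeq2 21, voom 572), 0, with 903, 1660 and 13, in NaKtide vs scrambled cells (DESeq2 3, voom 0) and 8, with 1098, 2183 and 10, in scrambled vs control cells (DESeq2 0, voom 369). In Kidney they were 9805, with 1049, 10436 and 45, in control cells vs PNx (DESeq2 20, voom 2088), 7559, with 3116, 8884 and 12, in NaKtide cells vs PNx (DESeq2 0, voom 6773) and 55, with 819, 3547 and 18, in NaKtide vs scrambled cells (DESeq2 14, voom 4401). In VFAT they were 1114, with 442, 3083 and 34, in control cells vs PNx (DESeq2 21, voom 39) and 2335, with 652, 5499 and 46, in NaKtide cells vs PNx (DESeq2 28, voom 3795). Chance cannot be excluded in any of the 9. The counts from 677 up point to a structure of the samples within the arms compared. For the set of PNx-changed genes in NaKtide vs scrambled cells, 29 of 100 splits had a fry p as low as the real 0.731 in Heart (lowest other 0.540). In Kidney 1 was as low as 0.200 (lowest other 0.224), and in VFAT 85 were as low as 0.942 (lowest other 0.350). Only in Kidney did no other split reach the real value, and there the fry p itself does not pass and the lowest other was close.

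Differences of the PNx effect between tissues were tested directly, with Heart Sham 2 and 3 and VFAT Sham 1, 3, 4 and 5 (high in genes of other tissues) among the libraries. In Kidney minus Heart 17 genes were called, 3 of 100 splits called as many and the highest other called 847, several times the real count, which points to a structure of the samples. In VFAT minus Heart 841 were called, 5 splits called as many (highest other 1218) and chance cannot be excluded. In VFAT minus Kidney 1131 were called and 2 splits called as many (highest other 2088), but 7 reached the real 4244 genes at an unadjusted p under 0.05 (highest other 5794), so chance stays open. At that p the real 5082 genes of Kidney minus Heart were reached in 2 splits and the real 3780 of VFAT minus Heart in 5. With the number as a random replicate block 0, 63 and 425 genes were called in the 3 tests. The genes named in these tests differed by −2.17 (Coq10b), 1.49 (Adprhl2) and 1.72 (Mmp15), by −6.49 (Kcnj11), −6.43 (Slc7a5) and 1.85 (Asap3), and by −10.82 (Spink8), −8.71 (Rpl3l) and −6.56 (Clu) on the log2 scale.

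A single library lay far from the rest of its group in 26 of 281 groups of a named gene, where chance gives about 1 in 20 groups, or 14, and the value given is the gap to the nearest library over the range of the group. Kidney PNx 3 was highest for Lcn2 (0.765, 1137 CPM against 6.77 to 22.9 CPM in the others), Rac2 (0.838, 102 against 2.67 to 4.92), Coro1a (0.736, 206 against 6.76 to 16.8) and Gc (0.743, 171 against 21.3 to 36.4). It was lowest for Slc7a13 (0.873, 89.5 against 352 to 429), Slc27a2 (0.822, 917 against 1865 to 2174), Slc6a19 (0.769, 101 against 186 to 223) and Src (0.802, 32.0 against 39.8 to 42.0). VFAT Sham 2 was lowest for Ceacam10 (0.853, 0.351 against 141 to 364), Gpx5 (0.79, 235 against 6190 to 14730), Lcn5 (0.757, 4.38 against 646 to 3158) and Sdf2l1 (0.742, 5.26 against 72.2 to 178). VFAT PNx 2 was highest for Manf (0.851, 84.4 against 46.5 to 50.8), Adam7 (0.734, 21.9 against 0.165 to 0.908) and Cst11 (0.713, 4.36 against 0 to 0.304). Kidney NaKtide cells 1 was highest for Cry2 (0.766, 31.2 against 16.2 to 18.9) and lowest for Src (0.757, 30.3 against 36.3 to 38.5). In Kidney the others were Cdk1 in PNx 5 (0.76, 6.31 against 4.14 to 4.59), Birc5 in Sham 2 (0.823, 0.560 against 1.04 to 1.18), Olfm3 in Sham 5 (0.758, 5.51 against 10.4 to 12.8) and Slc27a2 in Sham 4 (0.801, 3360 against 2881 to 2971). In Heart they were Col1a1 in scrambled cells 3 (0.797, 576 against 121 to 166), Kap in PNx 5 (0.781, 3.93 against 9.52 to 12.2) and Nppa in Sham 4 (0.811, 15.2 against 68.7 to 97.3). In VFAT they were Ucp1 in scrambled cells 3 (0.959, 1.14 against 21.2 to 23.9) and Sfrp5 in NaKtide cells 5 (0.834, 8.91 against 67.5 to 101).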

How the results depend on the processing

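The fits with an RNA length index or tissue scores as covariates, and those without the 11 libraries in doubt, were chosen only after the data were seen. Counts are of called genes, values beside gene names are log2 fold changes, and the cause of each move was not tested unless given.

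With DESeq2 the counts were 258 (Heart PNx vs Sham), 3 (Heart control cells vs PNx), 21 (Heart NaKtide cells vs PNx) and 3 (Heart NaKtide vs scrambled cells). In Kidney they were 4486 (PNx vs Sham), 20 (control cells vs PNx), 14 (NaKtide vs scrambled cells) and 89 (scrambled vs control cells). In VFAT they were 21 (control cells vs PNx), 28 (NaKtide cells vs PNx), 1589 (NaKtide vs scrambled cells) and 1094 (scrambled vs control cells), and in the interactions 2287 (Kidney minus Heart), 1539 (VFAT minus Heart) and 1708 (VFAT minus Kidney). With voom and quality weights Heart gave 0 (PNx vs Sham), 572 (NaKtide cells vs PNx) and 369 (scrambled vs control cells). Kidney gave 7232, 2088, 6773, 4401 and 1489 in PNx vs Sham, control cells vs PNx, NaKtide cells vs PNx, NaKtide vs scrambled cells and scrambled vs control cells, and VFAT 4647, 39, 3795, 841 and 0 in the same order. There the signs turned of Src (−0.00556), Myh6 (−0.0144) and Nppa (−1.59) in Heart NaKtide vs scrambled cells, and in VFAT of Ccl2 (0.55 in NaKtide vs scrambled cells, −0.12 in PNx vs Sham) and Ppargc1a (0.88 in NaKtide vs scrambled cells).

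With DESeq2's size factors only Kidney minus Heart moved by over 1.5 times (718). Without a filter the counts were 76 (Heart PNx vs Sham), 1007 (Kidney PNx vs Sham), 1 (Kidney scrambled vs control cells), 8 (Kidney minus Heart) and 544 (VFAT minus Heart), more genes being tested, while Ppargc1a turned to 0.0560 in VFAT NaKtide vs scrambled cells and the Heart set of PNx-changed genes turned (fry p of 0.761). With only the 2 arms compared in the fit, which leaves fewer samples, the counts were 1 (Heart PNx vs Sham), 146 (Kidney PNx vs Sham), 0 (Kidney scrambled vs control cells), 384 (VFAT PNx vs Sham), 1 (VFAT NaKtide cells vs PNx), 65 (VFAT NaKtide vs scrambled cells) and 45 (VFAT scrambled vs control cells). Ppargc1a was 0.0552 there in VFAT NaKtide vs scrambled cells, and the Kidney set passed (fry p of 0.00142). That set also passed with the 200 genes of lowest p (0.0140) and with genes of adjusted p under 0.01 (0.00635). With the second libraries of number 3 kept separate, the counts were 4283 (Kidney PNx vs Sham) and 1341 (Kidney minus Heart), Ppargc1a was 0.0915 in VFAT NaKtide vs scrambled cells, and the VFAT set turned (fry p of 0.985).

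The replicate numbers did not pair the libraries. The correlation of deviations between same-numbered libraries averaged 0.343 in Kidney control cells vs PNx (−0.483 to 0.722 over 5 pairs) and 0.216 in Heart NaKtide cells vs PNx (−0.244 to 0.495), and in no comparison was every pair over 0.1. No comparison had every library correlating best with its own number. With the number as a replicate block the counts were 0 in Heart PNx vs Sham, 2803 in Kidney PNx vs Sham, 0 in Kidney scrambled vs control cells, and 1654, 179 and 94 in VFAT PNx vs Sham, NaKtide vs scrambled cells and scrambled vs control cells, and Nppa was −2.06 in Heart NaKtide vs scrambled cells. The block ended 1 list call, that of adipocyte genes in VFAT PNx vs Sham (fry adjusted p of 0.0603). With the number as a random replicate block across tissues (consensus correlation −0.102), the interactions gave 0, 63 and 425 in Kidney minus Heart, VFAT minus Heart and VFAT minus Kidney.

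With the RNA length index as a covariate the counts were 12 (Heart PNx vs Sham), 546 (Kidney PNx vs Sham), 18 (Kidney control cells vs PNx), 209 (Kidney scrambled vs control cells), 3608 (VFAT PNx vs Sham) and 946 (VFAT NaKtide vs scrambled cells). Signs turned in NaKtide vs scrambled cells of Heart Src (−0.0632), Nppa (−0.99) and Myh7 (−0.0378) and Kidney Src (−0.0132), the Heart set turned (fry p of 0.509) and the Kidney set passed (0.0316). Without the libraries in doubt, which leaves fewer samples, the counts were 0 (Heart PNx vs Sham), 97, 2 and 228 (Kidney PNx vs Sham, NaKtide vs scrambled cells and scrambled vs control cells), 957, 15 and 13 (the same comparisons in VFAT) and 0, 183 and 208 in the 3 interactions. Turned signs there were Lep (−0.53), Ccl2 (−0.21) and Ppargc1a (−0.10) in VFAT PNx vs Sham, and Ccl2 (0.76) and Ppargc1a (1.24) in VFAT NaKtide vs scrambled cells. The Heart set turned (fry p of 0.689) and the Kidney set passed (0.000124). VFAT Sham 3 and 5 and scrambled cells 1 and 3, also with high tissue scores, stayed in. Of the calls of lists, 6 in Kidney and 7 in VFAT were lost without the libraries in doubt, 5 and 7 with only the 2 arms in the fit, and 3 and 2 with the RNA length index.

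With tissue scores as covariates 0 genes were called in Heart PNx vs Sham and in VFAT PNx vs Sham, NaKtide vs scrambled cells and scrambled vs control cells, and 2 in Heart NaKtide cells vs PNx. The covariates hold the muscle, pancreas and epididymis lists themselves, so the signs of their genes carry little. Signs turned in Heart of Fxyd2 (0.12) in PNx vs Sham and of Nppa (−0.72) in NaKtide vs scrambled cells. In VFAT PNx vs Sham they turned for Adipoq (−0.16), Ccl2 (−2.08), Ceacam10 (8.82), Csf1r (−0.41), Fabp4 (−0.21), Lcn5 (1.07), Lep (−1.30), Ppargc1a (−1.04) and Rrm2 (0.45). The adipocyte (fry adjusted p of 0.881), adipokine (0.995), cell cycle (0.937), macrophage (0.913) and unfolded protein (0.881) lists turned as well. In VFAT NaKtide vs scrambled cells Actn3 (2.56), Casq1 (2.66), Ccl2 (0.70), Cela1 (2.55), Myoz1 (1.08), Ppargc1a (1.79), Pygm (1.70) and Tnni2 (0.12) turned, and in scrambled vs control cells Actn3 (−1.76) and Myh4 (−0.68).

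Leaving out each library in turn gave counts of 0 to 377 (Heart PNx vs Sham), 0 to 1 (Heart scrambled vs control cells), 307 to 6534 (Kidney PNx vs Sham), 0 to 3 (Kidney scrambled vs control cells), 1089 to 4057 (VFAT PNx vs Sham), 147 to 740 (VFAT NaKtide vs scrambled cells) and 129 to 647 (VFAT scrambled vs control cells). The interactions gave 0 to 3143 (Kidney minus Heart), 452 to 2182 (VFAT minus Heart) and 746 to 2880 (VFAT minus Kidney). The fry p of the sets ran from 0.424 to 0.983 in Heart, 0.00245 to 0.402 in Kidney and 0.670 to 0.997 in VFAT. In Heart, Col1a1 ran from −0.0138 to 1.29 in PNx vs Sham, and in NaKtide vs scrambled cells Myh6 from −0.0238 to 0.0798, Src from −0.0421 to 0.25 and Nppa from −3.93 to 2.20. In Kidney NaKtide vs scrambled cells Col1a1 ran from −0.64 to 0.28 and Src from −0.0415 to 0.0868. In VFAT PNx vs Sham Ppargc1a ran from −0.0430 to 0.39, Ccl2 from −0.13 to 0.69 and Lep from −0.17 to 0.62, and in NaKtide vs scrambled cells Ppargc1a from −0.38 to 0.52 and Ccl2 from −2.38 to 0.85. Leaving out 1 library turned no sign of a gene called in all libraries. Without Kidney control cells 5, the shallowest library at 1241590 counts, control cells vs PNx stayed at 0 genes and scrambled vs control cells had 1.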

Other observations

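The genes picked from single libraries here were chosen only after their values were seen, while the lists were fixed beforehand.

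Genes of neutrophils and of the atria varied between single hearts. The 4 neutrophil genes tested in Heart PNx vs Sham were all higher (4 rose adjusted over the list alone, 0 over all genes, limma fry adjusted p = 0.482), with a median log2 fold change of 4.76. Levels of single libraries here are CPM of the plain library total. S100a8, a calcium-binding protein of neutrophils, measured 329.5 CPM in Heart PNx 1, 154.8 CPM in Heart PNx 2 and 219.9 CPM in Heart scrambled cells 3, against at most 3.61 CPM in the other 22 Heart libraries. Myl7, the atrial light chain of myosin, measured 1109 CPM in Heart PNx 5, 1464 CPM in control cells 1, 1944 CPM in NaKtide cells 5 and 1383 CPM in scrambled cells 4, and at most 175.4 CPM elsewhere in Heart. Nppa measured 1595, 2018, 2624 and 1813 CPM there in that order, and at most 397 CPM elsewhere.

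In the kidney after PNx, 7 of 7 pancreas genes and 10 of 10 liver genes were higher than after sham surgery. Of the pancreas genes 1 rose (4 adjusted over the list alone, fry adjusted p = 0.0503) and of the liver genes 2 (2 adjusted over the list alone, fry adjusted p = 0.139). Of 21 fatty acid oxidation genes 4 fell and 0 rose (4 adjusted over the list alone, fry adjusted p = 0.0905), and of 9 podocyte genes 1 fell (3 adjusted over the list alone, fry adjusted p = 0.0914). The inflammatory list had 3 rises among 12 genes (3 adjusted over the list alone, fry adjusted p = 0.175). The interferon list had 3 among 20 (4 adjusted over the list alone, fry adjusted p = 0.347).

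In visceral fat, 16 of 16 inflammatory genes were lower with NaKtide cells than with scrambled cells, and 5 fell over all genes (11 adjusted over the list alone, fry adjusted p = 0.326). Of 4 neutrophil genes 3 fell, of 20 interferon genes 2 and of 13 lipogenesis genes 2. Adjusted over the list alone 4, 9 and 8 did (fry adjusted p = 0.127 each). All 24 oxidative phosphorylation genes were lower and 0 passed (0 adjusted over the list alone, fry adjusted p = 0.127). Muscle or pancreas genes were high with scrambled cells, so the source of all these falls is open. After PNx without cells, 3 of 11 brown fat genes fell relative to sham surgery (6 adjusted over the list alone, fry adjusted p = 0.267), and 4 of 16 NRF2 target genes rose and 1 fell (5 and 2 adjusted over the list alone, fry adjusted p = 0.0531). Albumin, made by the liver, measured 2797 and 4430 CPM in VFAT control cells 3 and 5, 1187 CPM in VFAT PNx 3 and at most 323 CPM in the other VFAT libraries. Pbsn, a secreted protein of the prostate, measured 85.6 and 192.7 CPM in control cells 3 and 5 and at most 2.97 CPM in the others.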
